A study of Mus musculus with 10 samples.

How the data were processed

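ATAC-seq libraries were made by the submitters from mouse embryonic fibroblasts (MEFs) infected with retroviruses carrying a Flag control, Sox2, Klf4, Oct4 or the Oct4 mutant L80A, alone or in combination. Each of the 10 conditions has 1 library. The values come from a table deposited by the authors, which gives a signal for 21965 Ensembl genes in 20 columns, 2 columns per condition. The deposited signal was treated as a density over each gene. The window in which reads were counted and the scaling between libraries are not given in the sources used here. The submitters' processing notes give build mm10 and name Trimmomatic 0.35, cutadapt 1.13, Bowtie2 2.2.5, SAMtools 1.3.1, Picard, MACS2 2.1.0, deepTools, bedtools 2.25.0 and DESeq2 1.22.2. The step each tool served is not given in the sources used here.

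The relation of the 2 columns of a condition is also not given in the sources used here. They were treated as repeat measurements of 1 sample and counted as 1 replicate, and both values are given for the main genes. No number of reads per library is given in the table, so the depth behind each value is unknown and no counting interval was computed. With 1 library per condition there is no replicate error, and no significance test was made.

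Differences were computed as log2 of the signal plus a pseudocount of 0.138, the 10th percentile of all values above 0, and averaged over both columns. A gene was called higher or lower when the difference was at least 2-fold and the higher of the compared values reached 6.92, the median of all values in the table. Folds are printed on the scale that includes the pseudocount. Because the median of all genes moved between libraries, each difference is also given relative to the median of all genes in that comparison. The 9 comparisons were Oct4, Sox2, Klf4 and SKO against Flag, Oct4-L80A against Oct4, SKO-L80A and SKO+shBrg1 against SKO, and SKO-L80A+Vc and SKO-L80A+Ga against SKO-L80A. The conditions, comparisons, alternatives, 14 gene lists and the rule for named genes were chosen before the data were examined.

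The named genes were the 5 with the largest change in each direction of each comparison among genes past the size rule, at most 3 per gene list and direction past the size rule, and a fixed group of factor, pluripotency, epithelial and fibroblast genes. Not every gene that the rule gives is reported. A gene named in 1 comparison is followed in others where its values bear on them. Other genes, in the closing observations, were chosen after their values were seen. The lists were pluripotency network, fibroblast identity, AP-1 and TEAD factors, epithelial and MET (mesenchymal-to-epithelial transition), trophectoderm, primitive and definitive endoderm, neural, blood and endothelial cells, muscle, cartilage and bone, 2-cell-like and germline, Brg1 complex members, heterochromatin and DNA demethylation factors, interferon and stress response, and housekeeping. A stratified epithelium list was added after the Klf4 values were seen and leaves out the genes seen at the top of that comparison. In addition, 21 gene families were taken by symbol. The median of each list was set against 10000 random gene lists matched on 10 bins of mean signal, and its excess over their median and its percentile are given. Percentiles at or below 2.5 and at or above 97.5 are called outside the limits of matched lists. Matched lists do not stand in for replicates, since genes of a list can move together.

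Genes that changed in 1 comparison were followed as a set in comparisons sharing no library with it. Pearson and Spearman correlations of differences were computed across genes for 8 pairs of comparisons. Genes were also split into 4 quartiles of Flag signal. The alternatives were a pseudocount 4 times larger or 4 times smaller, no minimum signal, quantile normalisation, differences relative to the median of all genes, and removal of the trend with mean signal by lowess (fraction 0.3, 3 iterations). For correlations, an alternative kept only genes at or above the median level. Each column alone was added as an alternative after the data were seen, as were the comparisons of Oct4 with Sox2 and of Oct4-L80A and the combined conditions with Flag, and the following of the Sox2 and Klf4 gene sets in Oct4-L80A against Oct4.

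Symbols were matched to the RefSeq annotation of GRCm38.p6, the assembly of build mm10. Of the symbols, 20788 matched, and a further 511 were found only as synonyms. Coordinates were taken for matched symbols only. The table holds 27 date-like gene names, 23 duplicated names, 380 genes whose values are identical to those of another gene, and 1 gene at 0 in every column; all were kept. The procedure was tested on simulated data with 50 changed genes per fold in 21965 genes. Changes were planted only in genes with at least 2.5 times the minimum signal in the reference library. Both columns were given the same noise, and no shift of all genes was added. The simulation therefore does not describe genes near the minimum, disagreement between columns or a shift between libraries. At 1.5-fold 0 of 50 genes were called in each comparison. At 2.5-fold 50 of 50 were called, except 48 for Sox2 against Flag, and the calls among unchanged genes were 2 for Sox2 against Flag, 3 for Oct4-L80A against Oct4 and 0 elsewhere. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.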

Results

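Chromatin accessibility was measured by ATAC-seq, in which a transposase places sequencing adapters into open DNA, in mouse embryonic fibroblasts (MEFs) given reprogramming factors by retrovirus. The conditions were a Flag control, Sox2, Klf4 and Oct4 each alone, the Oct4 mutant L80A alone (Oct4-L80A), Sox2, Klf4 and Oct4 together (SKO), and SKO with L80A in place of Oct4 (SKO-L80A). SKO was also combined with a short hairpin RNA against Brg1 (SKO+shBrg1), and SKO-L80A with vitamin C at 50 µg/ml (SKO-L80A+Vc) or with Gadd45a (SKO-L80A+Ga). Each condition had 1 library with 2 columns of gene signal, so differences carry no replicate error and are described by size. The signal summed to between 112439 and 370390 per column. On the log2 scale with the pseudocount, the Pearson correlation between the 2 columns of a condition lay between 0.979 and 0.992 across genes.

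The signal over the factor genes followed most of the labels. Sox2 (ENSMUSG00000074637, chromosome 3, 34649995 to 34652461), which encodes an HMG-box pluripotency factor, had a signal of 75.5 and 87.1 in the columns of the Sox2 library against 2.73 and 5.12 in Flag. Klf4 (ENSMUSG00000003032, chromosome 4, 55527137 to 55532475), a zinc finger factor of epithelia and stem cells, had 166 and 146 in the Klf4 library against 12.6 and 17.8 in Flag. Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506032 to 35510777), which encodes Oct4, had 30.8 and 24.2 in the library labelled Oct4 and 19.0 and 49.6 in Oct4-L80A, against 0.812 and 1.12 in Flag. The library labelled Oct4 also had a Sox2 signal of 62.9 and 55.2, which its label does not name, while Oct4-L80A had 2.37 and 5.47. Pou5f1 had 2.34 and 3.03 in the Sox2 library, above Flag in both columns but below the minimum signal, and 0.890 and 1.49 in Klf4. The source of this Pou5f1 signal was not tested. In SKO the signals were 72.2 and 59.8 over Sox2, 78.5 and 66.6 over Klf4, and 10.2 and 9.35 over Pou5f1. Gadd45a, the stress-response gene added as a factor, had 36.6 and 41.5 in SKO-L80A+Ga and 37.3 and 52.1 in SKO-L80A, so its signal did not separate these conditions. Smarca4, which encodes Brg1, had 24.4 and 16.6 in SKO+shBrg1 and 19.8 and 14.7 in SKO; accessibility at this gene does not measure a knockdown. Reads over exons of the 4 genes supplied as factors can come from the virus inserts as well as from the genes of the cells.

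**Figure D1:**
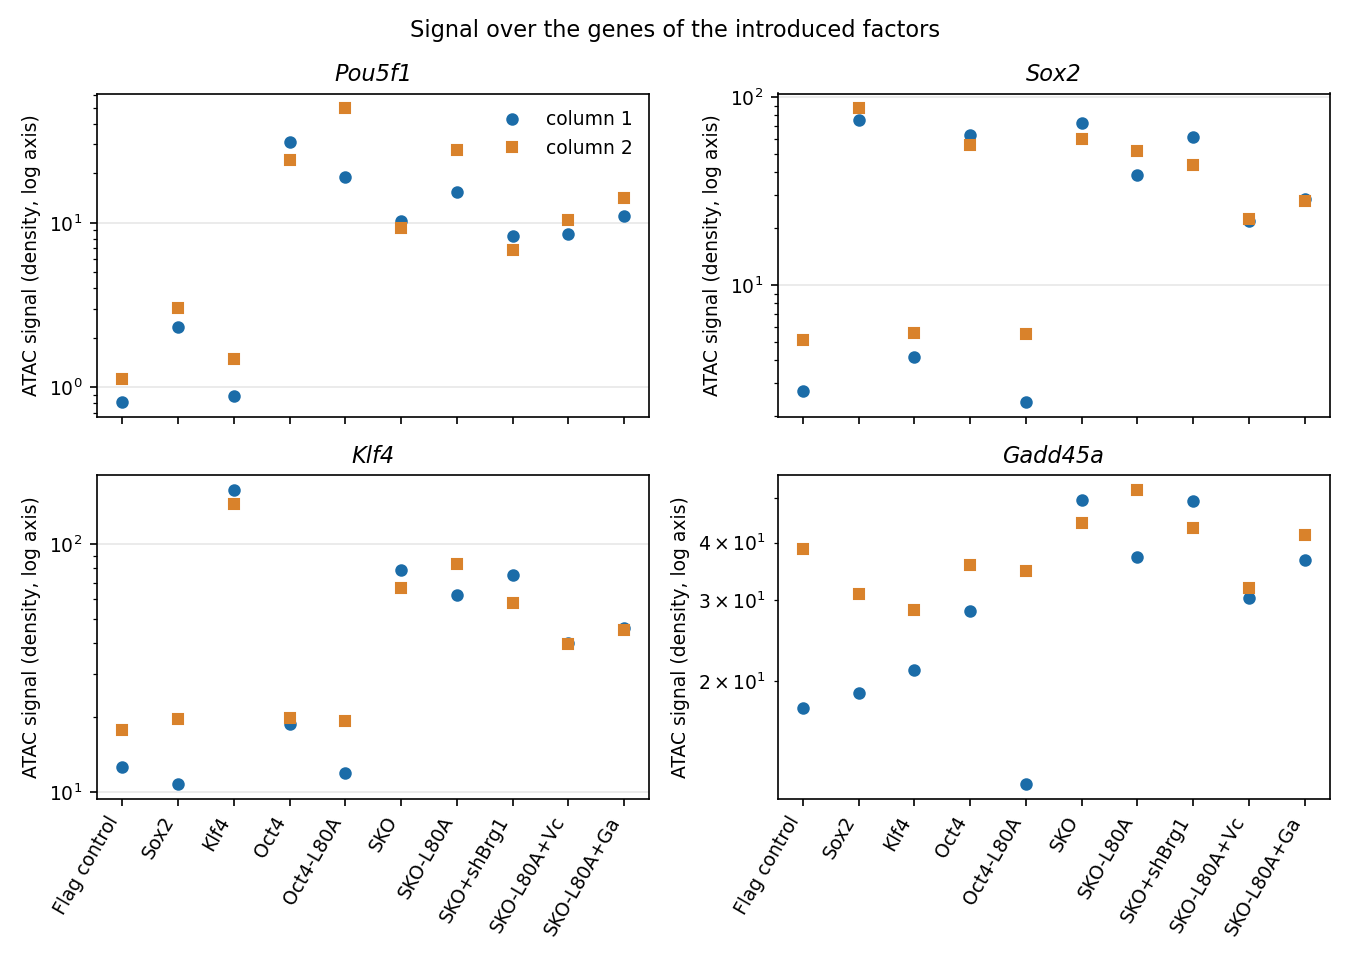
Deposited signal (log axis) over the factor genes in each of the 10 conditions, with a point for each of the 2 columns. Sox2 reads 62.9 and 55.2 in the library labelled Oct4 and 2.37 and 5.47 in Oct4-L80A.

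Sox2 alone was compared with Flag to see which genes gain or lose accessibility when this factor is given by itself. Sox2 was 20.9-fold above Flag, and the next genes were Adh7 (ENSMUSG00000055301, 3.54-fold), a retinol-oxidising dehydrogenase of epithelia, Tns4 (ENSMUSG00000017607, 3.18-fold), a focal adhesion protein, Agbl1 (ENSMUSG00000025754, 3.10-fold), a deglutamylase, and Shroom3 (ENSMUSG00000029381, 3.09-fold), an actin regulator of epithelial shape. Tns4 lies on chromosome 11 (99065678 to 99089306) and had 12.6 and 12.5 in Sox2 against 3.15 and 4.71 in Flag. Lox (ENSMUSG00000024529), the collagen cross-linking oxidase of fibroblasts, fell by 1.45 on the log2 scale, from 15.3 and 26.5 to 4.73 and 11.1. Fbln2, an extracellular matrix fibulin, fell by 1.10.

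Across genes, 13 were higher and 28 lower in Sox2 than in Flag, and 14 and 22 relative to the median of all genes, which moved by -0.09. The largest decreases were at Olfr957, an olfactory receptor (log2 difference -1.97), AL607142.1 (-1.69), Il2, a T-cell cytokine (-1.58), and Fcrlb, an Fc receptor-like gene of B cells (-1.46). Olfr957 (6.22 and 11.1 in Flag) and AL607142.1 (6.89 and 8.21) had more signal in Flag than in each of the 9 other conditions in both columns, so their decreases below do not single out a factor. The same limit holds for Cntf (8.28 and 10.4 in Flag), Vmn1r40 (8.25 and 14.2) and Gm4861 (8.98 and 15.8), which are named below. The fibroblast identity list, with 48 of its 50 genes in the table, had an excess of -0.19, below all 10000 matched lists, with Lox and Fbln2 past the size rule. It was -0.08 in column 1 (percentile 4.62, within the limits) and -0.22 in column 2. The lower values were not particular to fibroblast genes: the heterochromatin and DNA demethylation factors had -0.11 (percentile 0.25, but within the limits in column 2), the histone genes -0.24 and the ribosomal protein genes -0.13. The list and these 3 groups were negative in all 4 comparisons with Flag. Of the 42 genes in the pluripotency network only Sox2 passed the rule. Nanog, a core pluripotency factor, stayed at 0.545 and 0.563 in Sox2 against 0.562 and 0.793 in Flag.

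Klf4 alone was compared with Flag for the accessibility that goes with this factor. The Klf4 gene was 10.3-fold above Flag, and Cyp3a13 (ENSMUSG00000029727, chromosome 5, 137892933 to 137925610), a drug-metabolising cytochrome P450 of gut and liver, was 21.7-fold above it. Dydc2 (ENSMUSG00000021791, 9.40-fold), a DPY30-domain gene, Crocc2 (ENSMUSG00000084989, 8.40-fold), a ciliary rootlet gene, and Isx (ENSMUSG00000031621, 6.59-fold), an intestinal homeobox gene, followed. Cyp3a13 had 11.6 and 12.7 in Klf4 against 0.567 and 0.316 in Flag. Dsp, which encodes desmoplakin of epithelial junctions, was 2.19-fold higher. Myl9, a smooth muscle myosin light chain of contractile fibroblasts, fell by 1.62 on the log2 scale, and Thbs2, a matrix thrombospondin, fell by 1.16.

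In all, 163 genes were higher and 31 lower in Klf4 than in Flag, and 155 and 34 relative to a median shift of 0.03. Besides Myl9, the largest decreases were at Meikin, a meiotic kinetochore gene (-1.80), Vmn1r40, a vomeronasal receptor (-1.55), Zfp286, a zinc finger gene (-1.46), and Olfr957 (-1.40). The epithelial and MET list of 35 genes, of which 4 reached the minimum signal, had an excess of 0.27 (percentile 99.8), but 0.13 in column 1 alone (percentile 89.9). The stratified epithelium list of 45 genes, of which 10 reached the minimum signal, was added later. It had an excess of 0.36 (percentile 100 after rounding) with 4 members past the rule. Cdh1, the epithelial cadherin, had 2.60 and 4.38 in Klf4 and 1.36 and 1.86 in Flag, below the minimum signal, and Epcam, an epithelial adhesion molecule, had 1.56 and 2.59 against 1.28 and 1.79. Of the fibroblast genes, Thbs2 was the member past the rule, and the fibroblast identity list had an excess of -0.14 (percentile 0.25). Among other groups, the heterochromatin and DNA demethylation factors had -0.11 (percentile 1.19, but 4.40 in column 2, within the limits). Thy1, a fibroblast surface marker, had 1.98 and 3.24 in Klf4 and 3.01 and 5.46 in Flag.

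The library labelled Oct4 was compared with Flag for the accessibility that goes with Oct4 alone. E330017A01Rik (ENSMUSG00000055789), an uncharacterised gene without a RefSeq match, was 27.6-fold above Flag, with 8.47 and 7.94 against 0.196 and 0.135. Pou5f1 had a log2 difference of 4.65 and Sox2 of 3.93, or 15.2-fold. Pipox (ENSMUSG00000017453, chromosome 11, 77880614 to 77893872), a peroxisomal sarcosine oxidase, was 5.78-fold higher, and Il7r (ENSMUSG00000003882, chromosome 15, 9506159 to 9529941), the interleukin-7 receptor, was 4.82-fold higher. Since Sox2 was among these genes, the comparison does not separate Oct4 from Sox2.

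In the library labelled Oct4, 78 genes were higher and 5 lower than in Flag, so that 94.0% of calls were increases. Relative to a median shift of 0.18, 42 were higher and 14 lower, and the share of increases was 75%. Map2, a neuronal microtubule protein (log2 difference 1.24, 1.05 relative to all genes), Csf1r, a macrophage receptor (1.10), and Acta2, the actin of myofibroblasts (1.06), passed the rule, but Csf1r (0.91) and Acta2 (0.87) were under 2-fold relative to all genes. The 5 lower genes were Olfr957 (-1.30), AL607142.1 (-1.26), Susd1, a sushi-domain gene (-1.19), Opn1sw, the short-wave opsin (-1.15), and Tln2, which encodes talin 2 (-1.03). Besides Pou5f1 and Sox2, no member of the pluripotency network passed the rule. The fibroblast identity list had an excess of -0.13 (percentile 0.05), and Lox reached -1.05 relative to all genes. The housekeeping list of 30 genes had an excess of the same size, -0.12 (percentile 0.02), so the lower values were not particular to fibroblast genes. The heterochromatin and DNA demethylation factors, 32 genes such as Tet1, had an excess of -0.14, below all matched lists, with 0 members past the rule.

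SKO was compared with Flag for the accessibility of the 3 factors together. E330017A01Rik (47.5-fold), Crtam (ENSMUSG00000032021, chromosome 9, 40972798 to 41004628, 20.4-fold), an adhesion molecule of T cells, Sox2 (17.0-fold), Cyp3a13 (14.9-fold) and Ugt1a6a (ENSMUSG00000054545, chromosome 1, 88134809 to 88220002, 14.8-fold), a detoxifying glucuronosyltransferase, had the largest increases. Crtam had 15.8 and 9.30 in SKO against 0.388 and 0.548 in Flag. Gdf3, a TGF-beta family ligand of pluripotent cells, was 9.62-fold and Pou5f1 9.05-fold above Flag. Cldn3, a tight junction claudin, was 5.57-fold, Krt8, a simple epithelial keratin, 3.39-fold and Dsp 3.19-fold higher. The epithelial and MET list as a whole, with 5 of 35 members past the rule and 3 relative to all genes, had an excess of 0.02 (percentile 58.5), and -0.04 in column 1. The stratified epithelium list, with 11 of 45 members at the minimum signal, had 0.14 (percentile 96.1, within the limits). It had 0.34 in column 1 (percentile 99.8, outside the limits) and 0.13 in column 2 (percentile 93.8). Cdh1 had 1.56 and 2.43 against 1.36 and 1.86. Cntf, a ciliary neurotrophic factor, fell by 1.82 on the log2 scale.

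SKO had 1358 genes higher and 4 lower than Flag, with a median shift of all genes of 0.50. This shift was 0.97 in column 1 and 0.09 in column 2, and the number of higher genes was 8848 with column 1 alone and 247 with column 2 alone. Relative to the median of all genes, 288 were higher and 18 lower. Sox2 (3.58), Gdf3 (2.76), Pou5f1 (2.67), Cldn3 (1.97), Klf4 (1.75), Krt8 (1.26), Dsp (1.17) and Col2a1, the cartilage collagen (1.04), kept at least 2-fold on that scale. Tet1, a methylcytosine dioxygenase, had a log2 difference of 1.43 and was at 0.93 relative to all genes. The same held for Map2 (1.38, 0.87), Timp3, a protease inhibitor of matrix (1.33, 0.82), Dlx2, a homeobox factor (1.25, 0.75), Ccl2, a monocyte chemokine (1.24, 0.74), and Tubb3, the neuronal tubulin (1.23, 0.73). Smaller increases that also ended under 2-fold were at Smarcd1 and Dpf1 of the Brg1 complexes (1.05 and 1.16), the Hippo-pathway factors Tead3 (1.04) and Tead4 (1.02), the linker histone gene H1f0 (1.01), Irf7 of the interferon response (1.05) and the mesenchymal homeobox gene Prrx2 (1.05). Irf7 was at 1.01 in column 1 and 0.02 in column 2 relative to all genes.

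Several pluripotency genes stayed low in SKO. Nanog had 0.665 and 0.615 against 0.562 and 0.793 in Flag, Esrrb, an orphan nuclear receptor, 3.17 and 3.09 against 1.79 and 2.09, and Sall4, a zinc finger factor, 2.78 and 2.09 against 1.59 and 2.31. Among fibroblast genes, Col1a1, the main fibrillar collagen, had 28.3 and 20.4 in SKO and 19.8 and 24.7 in Flag. Twist1, a mesenchymal helix-loop-helix factor, had 18.1 and 17.7 against 11.8 and 18.0, and Prrx1, a mesenchymal homeobox factor, 8.34 and 5.51 against 4.22 and 7.07. The fibroblast identity list had an excess of -0.13 (percentile 0.07) and the heterochromatin and DNA demethylation factors -0.14 (percentile 0.05), though -0.04 in column 2 (percentile 16.4). Besides Cntf, the lower genes were Olfr957 (-1.32), AL607142.1 (-1.30) and Gm4861 (-1.02).

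**Figure D2:**
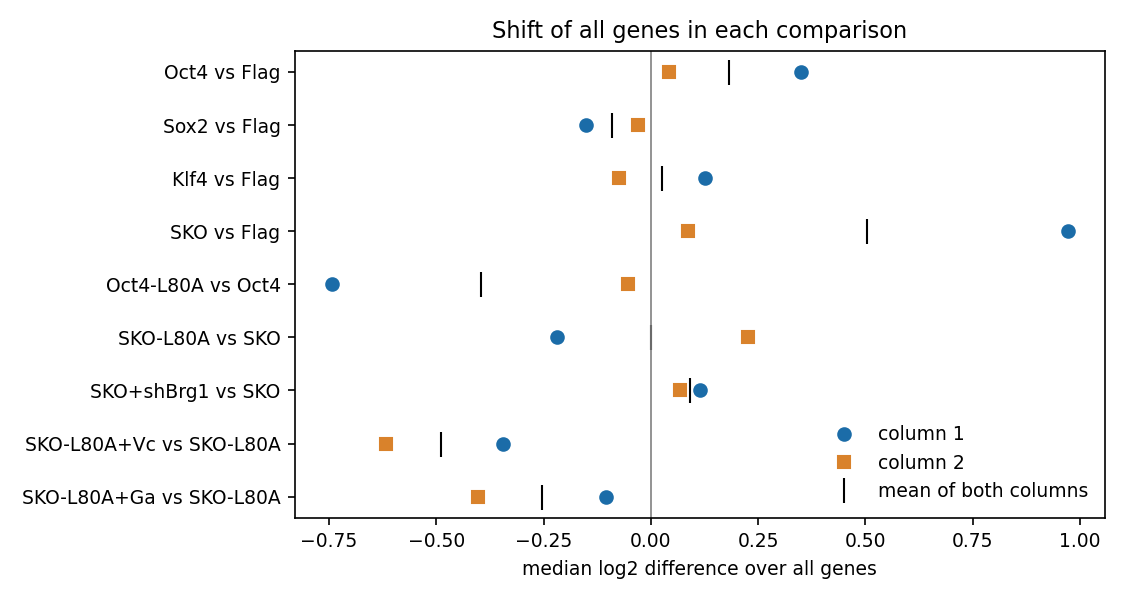
Median log2 difference of all 21965 genes in each of the 9 comparisons, for column 1, column 2 and their average. For SKO against Flag the columns read 0.97 and 0.09.

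Oct4-L80A was compared with the library labelled Oct4 to ask what the mutation changes. Sox2 was 15.7-fold lower in Oct4-L80A and E330017A01Rik 11.5-fold lower. Tns4 was 5.07-fold lower, with 1.47 and 3.46 against 12.5 and 11.6, and Bex3 (ENSMUSG00000046432), a brain-expressed X-linked gene, 4.80-fold lower. Pou5f1 had 19.0 and 49.6 against 30.8 and 24.2, so as signal the columns differed in opposite directions. The median of all genes was itself shifted by -0.74 in column 1 and -0.05 in column 2. The lower column 1 value is therefore not particular to the factor gene, while this shift does not account for the higher column 2 value. Since the library labelled Oct4 carried the Sox2 signal and Oct4-L80A did not, the comparison holds a Sox2 difference as well as the mutation.

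Of all genes, 0 were higher and 169 lower in Oct4-L80A than in the library labelled Oct4, with a median shift of -0.40 (-0.74 in column 1 and -0.05 in column 2). Relative to that shift 1 gene was higher and 44 were lower. The higher gene was Thy1 (1.19 relative to all genes), at 5.72 and 11.3 in Oct4-L80A and 3.57 and 5.89 in the library labelled Oct4. Csf1r (-1.09) and Lgals3, a galectin from the trophectoderm list (-1.05), were past the rule but at -0.69 and -0.66 relative to all genes. In comparisons of sets added after the data were seen, genes higher in Sox2 than in Flag had an excess of -1.26 in Oct4-L80A against the library labelled Oct4, below all matched sets. Genes lower in Sox2 had 0.51, above all of them, while genes higher in Klf4 had 0.00. The 288 genes higher in SKO relative to all genes had an excess of -0.30, below all matched sets. The fibroblast identity list had an excess of 0.07 (percentile 99.1, and 93.2 in column 1), and the neural list 0.13 (percentile 98.9), but -0.05 in column 2 alone.

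**Figure D3:**
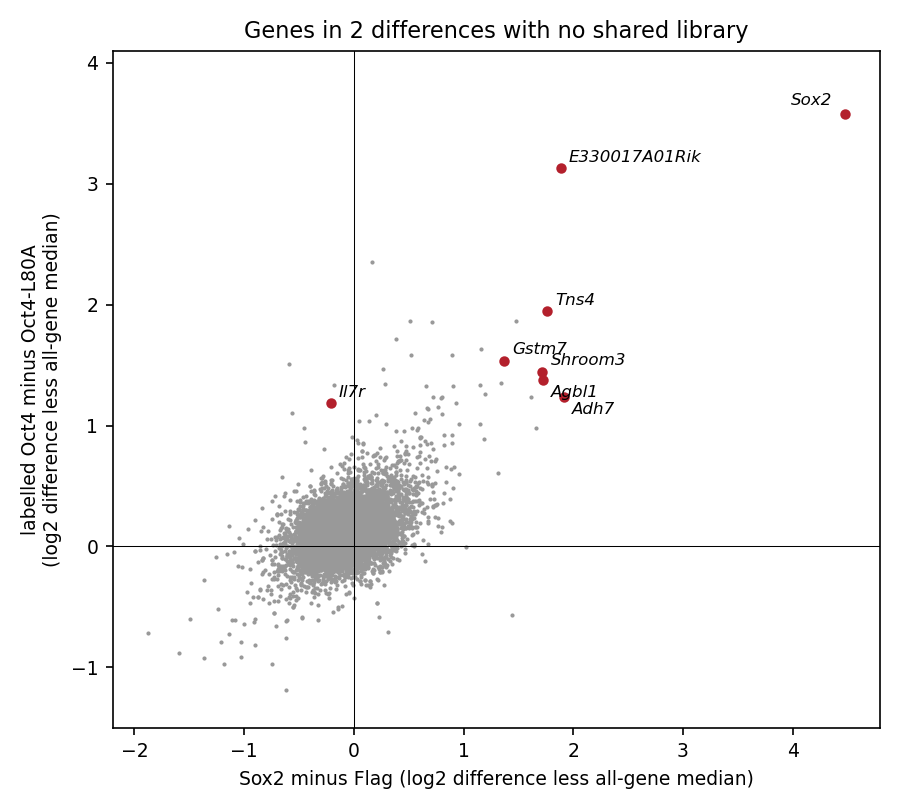
Each point is a gene, with its log2 difference of Sox2 minus Flag on the horizontal axis and of the library labelled Oct4 minus Oct4-L80A on the vertical axis, both relative to the median of all genes. Sox2 lies at 4.48 and 3.58, and across the 11240 genes shown Pearson's r was 0.480 (rho 0.358), and between 0.168 and 0.464 for single columns.

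SKO-L80A was compared with SKO to ask what the mutation changes when the other factors are present. Pou5f1, the gene of the exchanged factor, was 2.09-fold higher in SKO-L80A, with 15.4 and 27.5 against 10.2 and 9.35. Gm20594 (ENSMUSG00000096887, chromosome 6, 79818031 to 79818364), a predicted gene, was 5.07-fold higher, but its signal was 5.79 in column 1 and 36.8 in column 2 of SKO-L80A, and 1.82 and 4.20 in SKO. E330017A01Rik and Crtam stayed close to SKO, with 12.1 and 12.1, and 12.7 and 9.37. Pou5f1 and Gm20594 were the only 2 genes past the size rule, and 0 genes were lower.

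The differences of both columns correlated at r of 0.0831 across the 12590 genes that reached the minimum signal. The all-gene shift was -0.22 in column 1 and 0.23 in column 2. Genes higher in Sox2 than in Flag, such as Adh7 and Tns4, had an excess of -0.13 in SKO-L80A against SKO (percentile 0.14), and genes higher in Klf4 had 0.08, above all matched sets. Genes lower in Klf4, such as Myl9 and Meikin, had -0.09 (percentile 0.03). For the Sox2 genes the percentile was 5.42 in column 2. Genes lower in Oct4-L80A than in the library labelled Oct4 had -0.04 (percentile 0.02), which relative to all genes left 44 genes with -0.04 (percentile 5.91). Sox2 had 38.5 and 51.8 in SKO-L80A, at a log2 difference of -0.56 from SKO, and Nanog had 0.0918 and 0.483 against 0.665 and 0.615, all below the minimum signal. No list of the 14 lay outside the limits of matched lists.

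SKO+shBrg1 was compared with SKO for the effect of a hairpin against Brg1, the ATPase of SWI/SNF remodelling complexes. Gm20594 was the only gene past the rule, 4.12-fold higher, with 5.59 and 25.1 against 1.82 and 4.20. Its column 2 was also high with vitamin C (21.2) and Gadd45a (28.5), where column 1 had 3.37 and 3.27, and reads shared with repeated sequence were not tested as a source of this signal. Smarca4 had a log2 difference of 0.24, and the Brg1 complex members, 25 genes including Smarcd1 and Dpf1, had an excess of 0.04 (percentile 95.4) with 0 members past the rule. In column 1 alone these members had 0.07 (percentile 99.3, outside the limits), and in column 2 they had 0.03 (percentile 76.1). Pou5f1 (8.27 and 6.79) and Sox2 (61.5 and 43.6) stayed within 2-fold of SKO, as did Crtam (16.8 and 7.35) and Ugt1a6a (17.0 and 10.4). The fibroblast identity list had an excess of -0.05 (percentile 0.55), within the limits in each column alone (percentiles 12.1 and 12.6). Genes higher in the library labelled Oct4 than in Flag had -0.05 (percentile 0.27) and genes higher in Sox2 had -0.08 (percentile 1.95, and 24.0 in column 2). The all-gene shift was 0.09, and the differences of both columns correlated at r of 0.0972 across the 12776 genes that reached the minimum signal.

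Vitamin C, a cofactor of TET and histone demethylases, was added to SKO-L80A. Bbox1 (ENSMUSG00000041660, chromosome 2, 110264056 to 110314813), a dioxygenase of carnitine synthesis, was 3.15-fold lower with vitamin C, at 1.93 and 2.88 against 7.20 and 8.33. Olfr433, an olfactory receptor (-1.52), 6720489N17Rik, a predicted zinc finger gene (-1.43), Prom2, an epithelial prominin (-1.42), and Ly6d, a surface marker of keratinocytes and B cells (-1.41), were lower as well. The factor gene Pou5f1 (-1.11) and the matrix genes Lox (-1.02) and Dcn, which encodes decorin (-1.01), also passed the rule, as did Sox2 with 22.0 and 22.5 against 38.5 and 51.8.

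With vitamin C 0 genes were higher and 101 lower than in SKO-L80A, with a median shift of -0.49. Relative to that shift 2 genes were lower, Bbox1 (-1.17) and Olfr433 (-1.03), and Pou5f1 stood at -0.62 and Sox2 at -0.51. The epithelial and MET list had an excess of 0.16 (percentile 99.8), the 2-cell-like and germline list of 20 genes 0.23 (percentile 99.8), the AP-1 and TEAD factors 0.11 (percentile 99.9) and the housekeeping list 0.06 (percentile 98.8), each with 0 members higher. The fibroblast identity list, with Lox and Dcn lower, had 0.05 (percentile 97.8). In each column alone the epithelial, fibroblast and housekeeping lists lay within the limits, as did the AP-1 and TEAD factors in column 1, and 1 of the 20 genes of the 2-cell-like and germline list reached the minimum signal. Genes lower in SKO than in Flag relative to all genes, such as Cntf and Olfr957, had an excess of -0.34 with vitamin C, below all matched sets. Genes higher in SKO, such as Crtam and Ugt1a6a, had 0.00 (percentile 77.1), and the 288 that were higher relative to all genes had -0.03 (percentile 1.94).

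Gadd45a, a stress-inducible protein linked to DNA demethylation, was the other addition to SKO-L80A, and here 0 genes passed the size rule in either direction. Pou5f1 had 11.0 and 14.1 and Sox2 28.6 and 28.0, at -0.47 and -0.40 relative to a median shift of -0.25. Bbox1 had 4.13 and 4.43 and Cyp3a13 10.8 and 7.83, against 9.27 and 12.1 for Cyp3a13 in SKO-L80A. The neural list of 22 genes had an excess of 0.12 (percentile 99.8), and the epithelial and MET list 0.11 (percentile 99.5), which was -0.00 under quantile normalisation. Both lay within the limits in each column alone. Genes higher in SKO than in Flag had an excess of -0.04, below all matched sets, and those lower in SKO relative to all genes had 0.22, above all of them.

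Among the other lists, the trophectoderm list in SKO against Flag had an excess of 0.08 (percentile 83.0), the primitive and definitive endoderm list -0.11 (percentile 12.6), and the blood and endothelial list, with Csf1r and Coro1a past the rule but under 2-fold relative to all genes, 0.03 (percentile 58.6). The muscle, cartilage and bone list, with Col2a1 past the rule, had 0.00 (percentile 50.9), and the interferon and stress response list 0.11 (percentile 96.3). These 5 lists stayed within the limits of matched lists in all 9 comparisons. The pluripotency network had excesses of 0.05 in the library labelled Oct4, 0.12 in Sox2, 0.14 in Klf4 and 0.10 in SKO against Flag, all within the limits. In column 2 alone the network had 0.20 in the library labelled Oct4 (percentile 99.9), 0.26 in Klf4 (percentile 99.7) and 0.20 in SKO (percentile 99.7), outside the limits, and in column 1 it had -0.05, 0.12 and -0.00. The housekeeping list in SKO had -0.10 (percentile 0.42, and 8.01 in column 1), with Chmp2a past the rule (1.42, and 0.92 relative to all genes). The AP-1 and TEAD factors in SKO had -0.10 (percentile 2.24), within the limits in each column alone. Of 126 results from the 14 lists, 22 lay outside the limits, against 5% by chance for independent results.

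**Figure D4:**
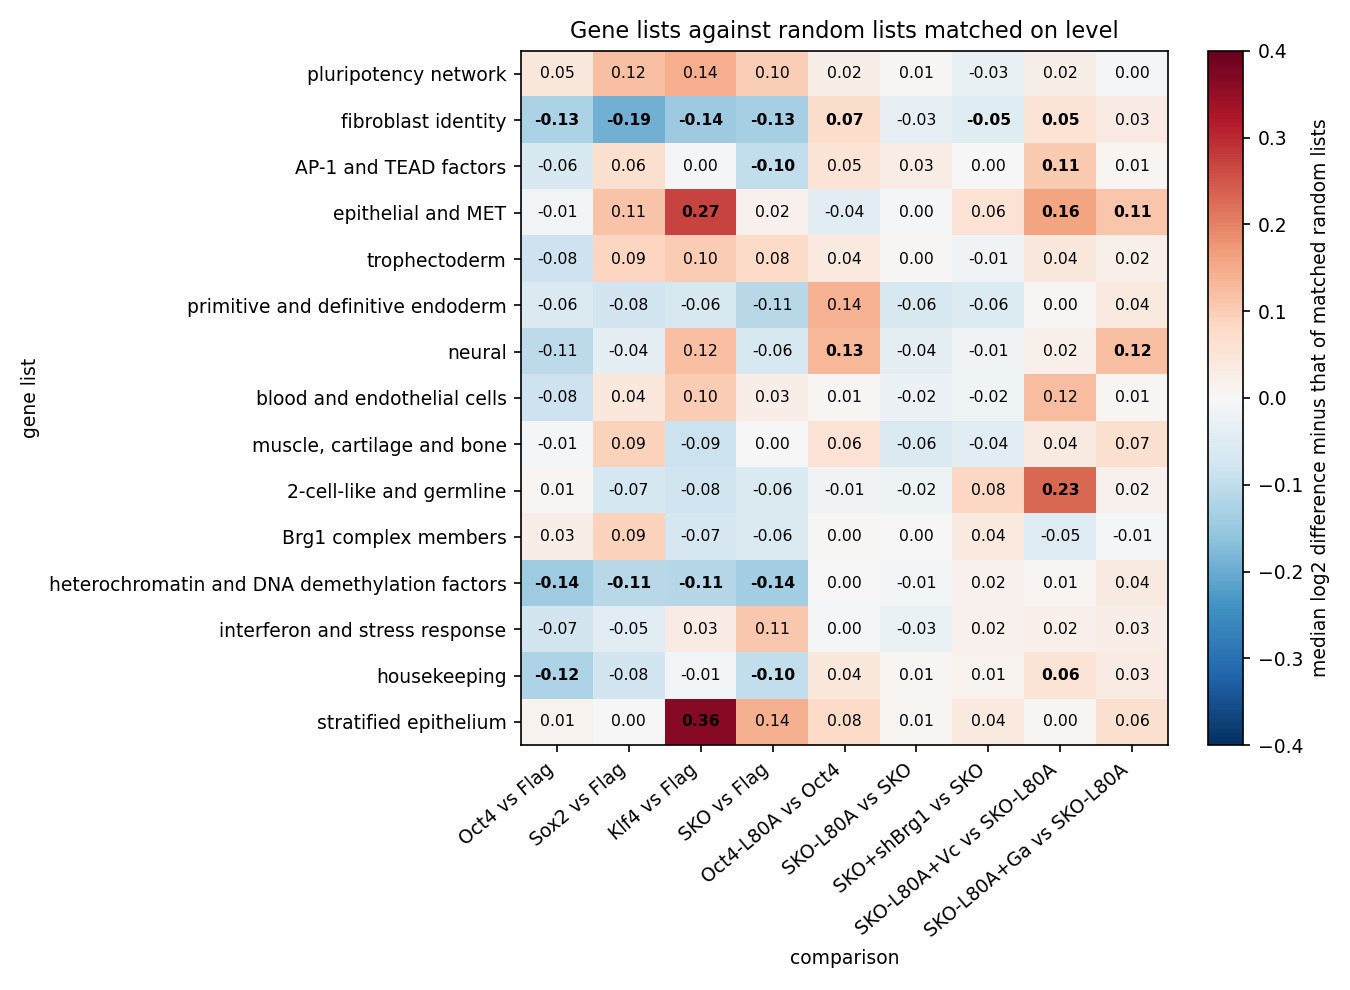
Excess of each gene list's median log2 difference over matched random lists, by list (vertical) and comparison (horizontal). The stratified epithelium list in Klf4 against Flag reads 0.36, and the fibroblast identity list reads -0.19 in Sox2 against Flag.

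The lower signal in Oct4-L80A and with vitamin C was spread over genes open in Flag. This does not separate a loss at genes from a difference between whole libraries. Over the 20 columns, the lower quartile of signal lay between 0.760 and 1.08 and the median between 3.38 and 11.8. A single scale factor per column would move both alike, so these values argue against it as the whole difference between columns. From the lowest to the highest quartile of Flag signal, the median log2 difference of Oct4-L80A against the library labelled Oct4 was 0.17, -0.32, -0.51 and -0.50, and that of vitamin C was -0.01, -0.47, -0.57 and -0.56. With Gadd45a it was 0.01, -0.24, -0.31 and -0.30, with the Brg1 hairpin -0.01, 0.12, 0.13 and 0.10, and for SKO-L80A against SKO between -0.00 and 0.01. In column 2 alone, the values for Oct4-L80A were 0.01, -0.11, -0.11 and -0.05.

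Differences were also correlated across the 21965 genes for 8 pairs of comparisons; genes are not independent replicates. The change that goes with wild-type in place of mutant Oct4 in SKO (SKO minus SKO-L80A) had r of 0.0563 (rho 0.0539) with the library labelled Oct4 minus Flag. It had r of 0.104 (rho 0.0722) with Sox2 minus Flag and -0.0873 (rho -0.0782) with Klf4 minus Flag. With the library labelled Oct4 minus Oct4-L80A, it had r of 0.0362 (rho 0.0315). None of these 4 kept its direction: the Sox2 value was -0.0837 in column 1, the Klf4 value 0.111 in column 2 and the value with Oct4-L80A -0.0577 in column 2. The value for the library labelled Oct4 minus Flag was -0.247 between column 1 of this difference and column 2 of the other. The library labelled Oct4 minus Oct4-L80A had r of -0.251 (rho -0.239) with SKO minus SKO+shBrg1. It was -0.0314 in column 2 and 0.0224 after quantile normalisation, so its direction was not kept. SKO minus Flag had r of 0.624 (rho 0.622) with the library labelled Oct4 minus Oct4-L80A, -0.476 (rho -0.477) with the vitamin C difference and -0.472 (rho -0.471) with the Gadd45a difference. The vitamin C correlation was -0.491 in column 1, -0.0513 in column 2 and -0.0162 over genes at or above the median level. For Gadd45a these values were -0.157, -0.133 and -0.158. The correlation of 0.624 was 0.718 in column 1, 0.335 in column 2, and 0.353 and 0.132 between a column of each kind.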

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

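All tests of explanations here, and the comparison of mutant effects at Agbl1, were chosen after the results were seen.

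Agbl1, a deglutamylase gene, differed in opposite directions between the L80A and wild-type libraries in the 2 settings, in both columns of each, when taken relative to all genes. It stood at -1.37 in Oct4-L80A against the library labelled Oct4 and at 0.28 in SKO-L80A against SKO. As signal it had 16.1 and 13.2 in SKO-L80A against 16.5 and 8.74 in SKO, so column 1 did not rise. The library labelled Oct4 carried a Sox2 signal and Agbl1 was 3.10-fold higher in Sox2 than in Flag, so the first value cannot be assigned to the mutation. The difference between the settings was not tested, since each condition has 1 library.

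The Sox2 gene had a high signal in the library labelled Oct4 but not in Oct4-L80A. Material from SKO cells would bring the genes of Klf4 with it, but the 154 genes higher in Klf4 (without Klf4) differed between these libraries by a median of 0.0626 relative to all genes, against 0.85 in SKO minus Oct4-L80A. The cells may also have carried the Sox2 virus, since the 13 genes higher in Sox2 (without Sox2), such as Adh7 and Tns4, had a median of 1.34, above all matched sets, which is as large as their median in Sox2 minus Flag. An opening of the cells' own Sox2 gene by Oct4, which would in turn raise Sox2 targets, cannot be told apart from this. The Sox2 signal was lower than in the Sox2 library by a log2 difference of -0.80 relative to all genes, and values per gene do not separate the virus insert from the locus.

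Genes lower in Oct4-L80A than in the library labelled Oct4 can reflect the mutation or other differences between these libraries. A difference in Sox2 is a candidate explanation for many of the lower genes: the 43 genes without Sox2 had a median of 0.72 in Sox2 minus Flag, above all matched sets, and 28 of them were at least 1.5-fold higher there, against 5.86% of all genes. A loss of Oct4 activity through L80A stays open. The 9 genes higher in the library labelled Oct4 than in Sox2 (without Pou5f1) had no gain as a set in Oct4-L80A minus Flag. Their median there was -0.27 relative to all genes (percentile 0.3 of matched sets), -0.13 in column 1 and -0.33 in column 2, with 4 of 9 above 0. Their median of 0.0491 in SKO-L80A against SKO, where SKO minus Flag gave 1.47, does not exclude such a loss, because Sox2 and Klf4 could stand in for Oct4 there. That too cannot be told, with a median of 0.44 in Klf4 minus Flag, since cells with Sox2 and Klf4 alone were not measured.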

How the results depend on the processing

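Each column alone was chosen after the data were seen, and where no reason is given below the cause was not tested. No paired analysis was possible because each condition has 1 library, and the alternatives that link regions to genes at 1 kb or 50 kb were not run because the table is per gene. The number of reads is unknown, so no limit from depth can be given. Counts of genes are given as higher and lower, and only those are given that left 1.5-fold of the reported count. Without a minimum signal more genes could be called by construction, with 307 and 71 for the library labelled Oct4 against Flag, 193 and 121 for Sox2, 638 and 87 for Klf4 and 2102 and 87 for SKO. Oct4-L80A then had 46 and 397, SKO-L80A 14 and 10, SKO+shBrg1 7 and 5, vitamin C 33 and 352 and Gadd45a 1 and 21. Quantile normalisation gave 27 and 26 for the library labelled Oct4, 20 higher for Sox2, 55 lower for Klf4, 124 and 39 for SKO, 8 and 34 for Oct4-L80A and 0 lower for vitamin C. Relative to the median of all genes the counts were 42 and 14 for the library labelled Oct4, 288 and 18 for SKO, 1 and 44 for Oct4-L80A and 2 lower for vitamin C. With the trend on mean signal removed they were 29 and 18, 185 and 27, 5 and 35, and 2 lower in the same order. These 3 settings remove the median shift of all genes, which was 0.50 in SKO and -0.49 with vitamin C. Subtracting the median does not remove the change of the shift with signal. With vitamin C the upper quartiles of Flag signal stood at -0.57 and -0.56. A pseudocount 4 times larger gave 63 lower genes with vitamin C. Column 1 alone gave 339 and 0 for the library labelled Oct4, 20 lower for Klf4, 8848 and 1 for SKO, 4240 lower for Oct4-L80A, 0 and 4 for SKO-L80A and 0 higher for SKO+shBrg1. Column 2 alone gave 50 and 23 for the library labelled Oct4, 21 and 60 for Sox2, 84 lower for Klf4, 247 and 24 for SKO, 4 and 41 for Oct4-L80A, 5 higher for SKO-L80A, 880 lower for vitamin C and 90 lower for Gadd45a. Correlations with SKO minus SKO-L80A moved to 0.274 for the library labelled Oct4 minus Flag and 0.356 for it minus Oct4-L80A in column 1. The latter was -0.0577 in column 2, and with column 1 of the first and column 2 of the second difference they were -0.247 and -0.351, so neither kept its sign. In column 1 the correlation reversed to -0.0837 for Sox2 minus Flag; for Klf4 minus Flag it was 0.111 in column 2. The correlation of the library labelled Oct4 minus Oct4-L80A with SKO minus SKO+shBrg1 was -0.0314 in column 2 and -0.0033 with the trend removed, and it reversed to 0.0076 over genes at or above the median level and to 0.0224 after quantile normalisation. For SKO minus Flag, the correlation with the vitamin C difference was -0.0162 over genes at or above the median level, -0.0666 after quantile normalisation, -0.0758 with the trend removed and -0.0513 in column 2. With the Gadd45a difference it was -0.158, -0.169, -0.171 and -0.133 in the same order, -0.157 in column 1, and -0.548 and -0.419 with the larger and the smaller pseudocount. With the library labelled Oct4 minus Oct4-L80A it was 0.335 in column 2. Among sets and lists, genes lower in Oct4-L80A reversed to an excess of 0.0015 in SKO+shBrg1 in column 1. The epithelial and MET list reversed to -0.0046 with Gadd45a after quantile normalisation, and the neural list to -0.0452 in Oct4-L80A in column 2. Of 23 list results, 12 moved without changing direction in column 1, 9 in column 2, 7 after quantile normalisation and 10 with the trend removed. Of 20 set results, 6 did so in column 1, 12 in column 2, 7 after quantile normalisation and 7 with the trend removed.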

Other observations

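The test of the shift of all genes and the groups of genes below were chosen after the results were seen.

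Some genes had more signal with the combination of factors than in Flag or in the libraries labelled with a single factor. Pairs of factors were not measured under their own label, so an effect of a pair is not separated from that of the full combination. F2, which encodes prothrombin, had 17.4 and 10.3 in SKO. It had between 1.14 and 2.05 in Flag, Sox2, Klf4, Oct4-L80A and the library labelled Oct4. Crtam, the LEM-domain gene Lemd1, Ugt1a6a, the protease inhibitor gene Serpina3i, Plekha6, the red-cell membrane gene Epb42, the serine protease gene Prss38, the acetyltransferase gene Nat3, the endoribonuclease gene Endou and the chloride channel regulator gene Clca2 completed a group of 11 genes. Each was at least 2-fold higher in SKO than in Flag, Sox2, Klf4 and the library labelled Oct4, relative to all genes. Single factors left some of them above Flag: Prss38 had 5.57 and 5.93 in Klf4 and at most 1.29 in Flag, and Crtam had 1.34 and 1.74 in Sox2 against 0.388 and 0.548. Ugt1a6a had 2.67 and 3.29 in the library labelled Oct4, which also had a Sox2 signal, against 0.759 and 0.776. At all 11 genes each of the 5 libraries with SKO or SKO-L80A was above each of the other 5 in both columns, including those with L80A and with the Brg1 hairpin. For SKO this largely follows from how the genes were chosen. Only Oct4-L80A and the combinations other than SKO played no part in that choice. Lemd1 had 24.2 and 15.7 in SKO, 19.1 and 20.2 in SKO-L80A, and at most 4.49 outside the 5 libraries with SKO or SKO-L80A.

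Genes higher in Klf4 mostly stayed open in the combinations. Relative to all genes, the 155 genes had a median of 1.29 in Klf4 minus Flag, 1.03 in SKO, 1.09 in SKO-L80A, 1.01 in SKO+shBrg1, 0.89 with vitamin C and 1.03 with Gadd45a. They had 0.18 in the library labelled Oct4, 0.09 in Sox2 and 0.02 in Oct4-L80A. Relative to all genes, 21 of the 155 were at least 2-fold lower in SKO than in Klf4. Most of these were under 2-fold lower as signal, such as Cyp3a13, with 11.6 and 12.7 in Klf4 and 8.14 and 8.45 in SKO. Dydc2 had 7.43 and 8.26 in Klf4 and at most 0.912 in any other library, and Crocc2 had 11.0 and 9.41 in Klf4 and at most 2.74 elsewhere. Prom2, an epithelial prominin, had 14.0 and 19.7 in Klf4 and 11.1 and 7.08 in SKO.

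Oct4-L80A differed little from Flag. Relative to all genes, Pou5f1 (4.98) and Thy1 (1.12) were higher, and the urea transporter gene Slc14a1 (-1.10) and the glycosyltransferase gene Gcnt2 (-1.03) were lower. The library labelled Oct4 had 10 genes higher and 0 lower than the Sox2 library, among them E330017A01Rik (2.65), Il7r (2.23), the potassium channel gene Kcnk7 (1.26), the neural membrane gene Ttyh1 (1.20), the complement gene C1s1 (1.15) and the cytokine gene Il34 (1.03). Against Flag, SKO-L80A had 287 genes higher and 18 lower, SKO+shBrg1 292 and 20, vitamin C 180 and 33, and Gadd45a 192 and 10, on the same scale. The minimum was applied to the signal before the median was removed, so libraries with less signal reach it at fewer genes. These counts therefore do not measure an effect of the additions. Directly against SKO-L80A, on the same scale, vitamin C had 0 higher and 2 lower and Gadd45a 0 and 0.

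Among the 21 families, 45 of 189 results lay outside the limits of matched lists, most with few or 0 members past the size rule. The 67 histone genes had an excess over matched lists of -0.17 in the library labelled Oct4, -0.24 in Sox2, -0.16 in Klf4 and -0.18 in SKO against Flag, and the 101 ribosomal protein genes -0.15, -0.13, -0.09 and -0.16. All of these were negative in each column alone and under both quantile normalisation and removal of the trend, all share the Flag library, and relative to all genes 0 members passed the size rule. In Klf4 the 100 cytochrome P450 genes had an excess of 0.21 and the 36 genes of the Sprr and Lce families of the cornified envelope 0.26, positive in each column and under the same alternatives. Cyp3a13 was the cytochrome P450 gene past the rule, and 0 of the 36 Sprr and Lce genes reached the minimum signal. The 57 keratin-associated genes had 0.18, but 0.02 in column 1, while the 53 keratin genes (-0.01, percentile 43.7) and the 33 claudin genes (0.12, percentile 93.5) stayed within the limits. Families far from epithelia were also positive in Klf4. The 1135 olfactory receptor genes had 0.10, positive in each column and under the same alternatives, though 0.07 in column 1 and 0.03 after quantile normalisation. Only 2 of them reached the minimum signal. The 69 protocadherin genes had 0.13, but 0.06 in column 2 (percentile 76.7, within the limits). The olfactory receptor genes had 0.10 in Sox2 as well, but 0.03 after quantile normalisation. In the library labelled Oct4 they had -0.09, but 0.07 in column 2 alone.

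The shift of all genes in SKO against Flag was 0.50. A biological opening of most genes in SKO would need a shift in both columns, and the smaller of the 2 was 0.0875. The median differences between the 2 columns of a condition had an SD of 0.41, so such an opening cannot be told apart from none. This SD is within conditions, and no spread between repeat libraries was measured. Against the same Flag library, the shift was 0.52 in SKO-L80A, 0.62 in SKO+shBrg1, 0.24 with Gadd45a and 0.02 with vitamin C. A share of signal over genes that varies between columns may explain the shift in SKO, since the 2 columns of Oct4-L80A differed by a median of 0.92. That is more than the shift of 0.50 averaged over both columns, but less than the 0.97 of SKO against Flag in column 1 alone.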
